A study of Arabidopsis thaliana with 6 samples.

How the data were processed

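Total RNA from Arabidopsis thaliana seedlings at Boyes growth stage 1.04 was measured by RNA sequencing in 6 libraries, 3 from wild-type plants and 3 labelled as a double mutant of AT4G15640 and AT3G21465. Per the labels' protocols, ribosomal RNA was depleted and libraries were made with a strand-specific total RNA kit and read from a single end. Per the submitters' processing notes, reads were aligned with STAR and counted with featureCounts on the TAIR10 genome; the versions of STAR and of the gene annotation are not given in the sources used here. The deposited values are raw read counts per gene, 1 table per library, counted with featureCounts 2.0.0 per the file headers. The options in the file headers show that reads were counted on the strand opposite to the read, summed over exons of each gene, and that a read with several alignments was counted at every one of them at full weight. A transcript with a near-identical copy therefore adds counts to both genes, and the total of a library counts alignments rather than reads. No read that overlapped exons of several genes on the same strand was assigned to any, which lowers the counts of overlapping genes.

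Groups and replicate numbers were taken from the genotype labels and titles. The series design text speaks of 2 biological replicates, whereas the titles number 3 libraries per genotype; all 6 libraries were used, 3 per group. Nothing in the labels says that the libraries of a group came from separate cultures or plants, so p-values measure only the spread between these libraries, which may be technical. Within a group, all pairs of libraries differed by more than sampling noise, with chi-square per degree of freedom between 11.3 and 39.8. Between groups this value lay between 198 and 334. It was scaled by library totals only, so differences in composition raise it too. It therefore cannot tell technical repeats from separate samples. No library was treated as a repeat of another.

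The tables held 32744 genes, of which 32548 were nuclear, 63 mitochondrial and 133 plastid. Gene names came from the TAIR10.1 reference annotation. All 32548 nuclear identifiers matched a locus tag, and 99.95% of them had the same chromosome, start and end in both. Of the 196 organelle genes, 190 were named by identical start or end and strand. Coordinates are given as in the deposited tables, on TAIR10. Exon sequences of all genes were compared with each other in the direction of transcription, and with the organelle genomes in both directions, with BLAST+ 2.17.0 (megablast, at least 95% identity over at least 50 bases). A shared exact stretch of 50 bases between 2 genes also counted as near-identical sequence. By this measure 4622 nuclear genes had a near-identical partner and 149 shared sequence with an organelle genome.

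Differences were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter, a quasi-likelihood fit with the group as the only term, a two-sided test and Benjamini-Hochberg adjustment over 21805 tested genes, with an adjusted p threshold of 0.05. CPM is the gene's count scaled to a TMM-adjusted library total of 1e6. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Fold changes are the libraries labelled double mutant over wild type. On counts simulated from these libraries' means, dispersions and sizes over 21805 genes, the fit recovered 54% of 50 genes changed by 0.5 on the log2 scale, 86% of 50 changed by 1, 94% of 50 changed by 2 and 94% of 50 changed by 3, and called 0.09% of 21605 unchanged genes. Far fewer genes were changed in the simulation than were called in the data (11421). The adjusted threshold depends on that share, so these rates need not hold for the data.

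Before the data were examined, 22 lists of nuclear genes were fixed, and the mitochondrial and the plastid genome genes made 24 lists. AT3G17465 was dropped from the mitoribosomal list because the reference names it a plastid protein; that comparison with reference names was made after a first fit had been run. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 24 lists. The same test with an estimated correlation, and fry, were run beside it. The genes named in the text follow a rule fixed at the same time. It took both targeted genes and AOX1A. It also took the 10 largest positive and 10 largest negative log2 fold changes. These were among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups. From each list it took up to 4 members with the smallest adjusted p among those under 0.05. The root, seed and floral marker lists gave at most 2. Other genes named were chosen after their values were seen; they include the called members of a list fixed beforehand where their number in a direction is 5 or fewer. The share of counts on each genome was compared by an exact two-sided permutation test of the difference in means over 3 comparisons, which cannot go below 0.1 with 3 against 3 libraries.

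Alternatives were DESeq2 1.42.0 size factors in the edgeR fit, the DESeq2 Wald test (with camera on its Wald statistic for the lists), limma-voom, no filter on low counts, nuclear genes only, the replicate number as a block, each library left out in turn, a 2-fold threshold, and the organelle shares without the organelle gene with the most counts. A fit without the 149 nuclear genes that share organelle sequence was added after seeing the data, as were 5 further gene lists. Exons, splicing and RNA editing were not resolved by counts per gene and are not analysed here.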

Results

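Total RNA depleted of ribosomal RNA from Arabidopsis seedlings was counted per gene in 3 wild-type libraries and in 3 libraries labelled as a double mutant of AT4G15640 and AT3G21465, which the series title describes as genes for uncharacterised mitochondrial proteins. The comparison asks which transcripts differ between the genotypes. Total counts were 53193772, 74340300 and 77446157 in the wild-type libraries and 78671470, 68633298 and 62235559 in the libraries labelled double mutant. The first principal component of log2 CPM held 83.7% of the variance and separated the groups. Pearson correlations across genes were at least 0.988 within groups and at most 0.947 between them; genes are not independent replicates.

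The targeted genes were examined first, because they check the labels. AT3G21465 (chromosome 3, 7560688 to 7563472, plus strand, 11 exons) was lower in the libraries labelled double mutant, at 4.61 ± 0.255 CPM (SD, n = 3) against 7.92 ± 0.4997 CPM (SD, n = 3) in wild type. Its log2 fold change was -0.78 ± 0.08 (SE; edgeR adjusted p = 8.95e-05), and 340 to 385 counts remained in each of these libraries. AT4G15640 (chromosome 4, 8918968 to 8921994, minus strand, 12 exons) was not lower: it had 13.4 ± 0.725 CPM (SD, n = 3) against 11.95 ± 1.07 CPM (SD, n = 3), a log2 fold change of 0.16 ± 0.08 (SE; edgeR adjusted p = 0.121). Without wild type replicate 2 this difference passed the threshold as an increase of 0.24 (edgeR adjusted p = 0.0338; range over all alternatives 0.0338 to 0.33). No other gene shared near-identical sequence with, or overlapped, either targeted gene. Counts over a whole gene do not show whether a transcript is intact, so they neither establish nor exclude an allele that leaves transcript behind. Because the level of AT4G15640 goes against a loss of that transcript, the second group is called the labelled mutant libraries, and every direction given here rests on that label. AOX1A (AT3G22370, chromosome 3, 7906521 to 7908746), the alternative oxidase that bypasses the cytochrome pathway, rose 2.46-fold, from 14.7 ± 1.71 to 36.03 ± 3.42 CPM (SD, n = 3 each; edgeR adjusted p = 1.54e-05).

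**Figure D1:**
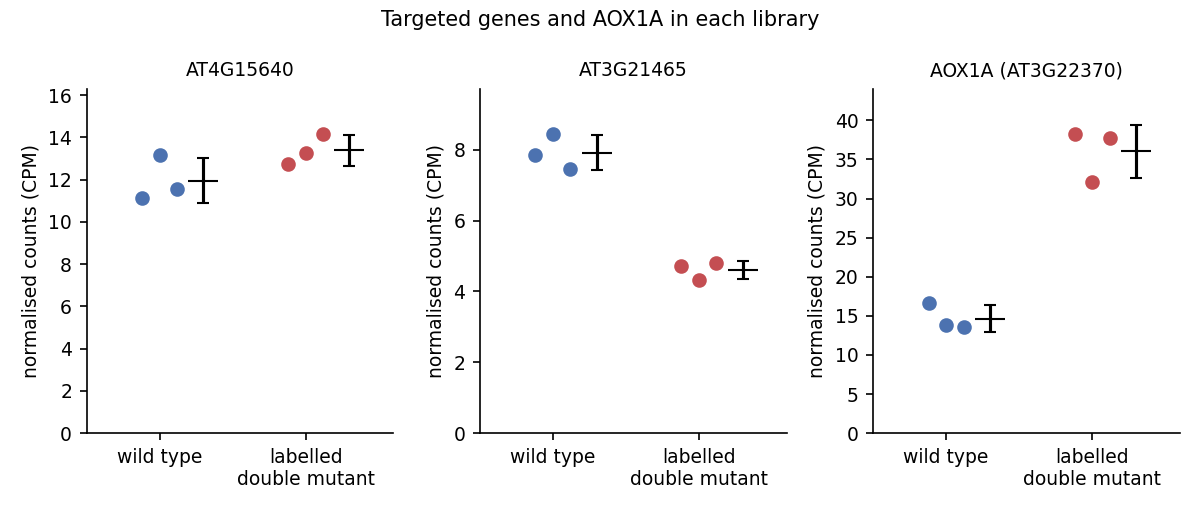
Normalised counts (CPM, linear axis from 0) of AT4G15640, AT3G21465 and AOX1A, each point a library, with the mean and SD of each group (n = 3) as a bar beside the points. The labelled mutant libraries lie below all wild-type libraries for AT3G21465 (means 4.61 and 7.92 CPM), above them for AOX1A (36.03 and 14.7 CPM), and overlap them for AT4G15640.

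Of 21805 tested genes, 5742 were higher and 5679 lower in the labelled mutant libraries at an edgeR adjusted p under 0.05, 11421 in all. Of these, 1538 were higher and 1427 lower by more than 2-fold. Over all tested genes, called or not, 13483 (61.8%) had no overlap between the groups, where chance gives 10%. The median log2 fold change of all tested genes was 0.01. TMM scaling centres fold changes on the bulk of genes, so this median and the numbers in each direction are relative to that centre.

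Among called genes with a mean of at least 5 CPM and no overlap between the groups, NUDT24 (AT5G19470), a nudix hydrolase, had the largest increase, from 0.107 ± 0.0789 to 89.9 ± 21.1 CPM (SD, n = 3 each), a log2 fold change of 9.66 ± 0.31 (SE; edgeR adjusted p = 3.44e-07); it shares a short stretch with NUDT20, which did not pass the test. AT5G09570, a Cox19-like protein gene, and NDB4 (AT2G20800), an external type II NAD(P)H dehydrogenase, had log2 fold changes of 7.59 ± 0.23 and 7.43 ± 0.20 (SE). GPT2 (AT1G61800), the plastid glucose-6-phosphate translocator, rose by 7.24 ± 0.41 on the same scale, from 0.247 ± 0.299 to 41.1 ± 8.88 CPM (SD, n = 3 each). The anthocyanin enzymes DFR (AT5G42800) and AT4G14090, a glycosyltransferase, rose by 6.53 ± 0.30 and 6.28 ± 0.20. The acyltransferase genes AT1G03495 (6.86 ± 0.19) and AT1G03940 (6.52 ± 0.24) share near-identical sequence, and the counting does not separate them. LTP4 (AT5G59310), a lipid transfer protein, and AT3G12900, a 2-oxoglutarate-dependent oxygenase, completed the 10 largest increases with 6.82 ± 0.24 and 6.24 ± 0.31. Most of these genes were under 1 CPM in wild type, so their fold changes rest on few wild-type counts. Without wild type replicate 2 the log2 fold changes of NUDT24, AT5G09570 and NDB4 were 10.5, 8.395 and 8.02, and without wild type replicate 3 that of GPT2 was 8.86.

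The largest decreases by the same rule ranged from -4.56 to -3.81 on the log2 scale. DIN10 (AT5G20250), a dark-inducible raffinose synthase family gene, went from 436 ± 91.0 to 19.4 ± 8.56 CPM (SD, n = 3 each), a log2 fold change of -4.49 ± 0.31 (SE; edgeR adjusted p = 9.10e-06). BXL1 (AT5G49360), a beta-xylosidase, had -4.37 ± 0.38. The BTB-TAZ domain genes BT2 (AT3G48360) and BT5 (AT4G37610) had -4.22 ± 0.21 and -3.93 ± 0.21, and AT3G15450 had -3.89 ± 0.18. The thioredoxin family gene AT5G18600 had the largest decrease by the naming rule, -4.56 ± 0.19. The gibberellin-regulated family gene AT1G22690 had -4.31 ± 0.12, AT1G50040 -3.95 ± 0.42 and the methionine sulfoxide reductase gene MSRB6 -3.91 ± 0.21. AT4G12510, a lipid transfer family gene with -3.81 ± 0.36, cannot be separated from its near-identical neighbour AT4G12520. Without double mutant replicate 2 AT1G50040 had -5.08, and without double mutant replicate 1 AT4G12510 had -4.42.

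**Figure D2:**
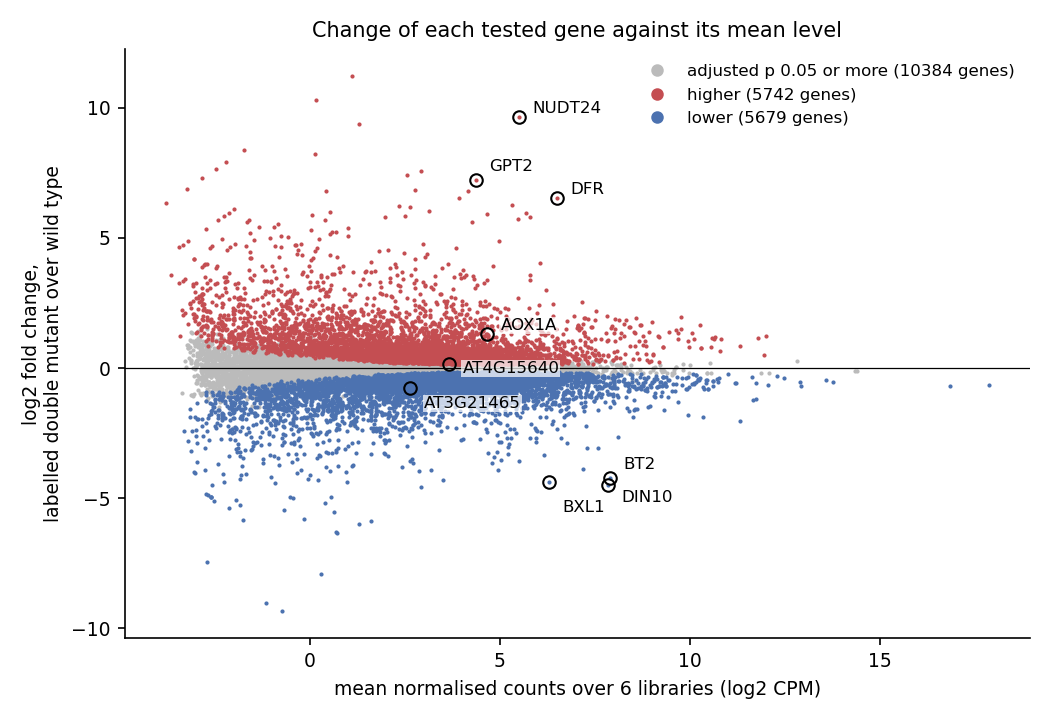
Log2 fold change of each of 21805 tested genes (labelled mutant over wild-type libraries) against its mean level over 6 libraries in log2 CPM. Genes with an edgeR adjusted p under 0.05 are red where higher (5742) and blue where lower (5679), and circles mark some of the genes named in the text, among them NUDT24 at 9.66 and DIN10 at -4.49.

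Of the 24 gene lists, 10 passed the camera test with the preset correlation, 6 as higher and 4 as lower. With a correlation estimated per list, the mitochondrial dysfunction stimulon alone passed, so p-values of the other lists rest on the preset correlation; the estimated value is given beside each list that passed here or in a camera alternative. Ranges over camera alternatives are with the preset correlation. The fry test, which asks whether a list's genes move on balance one way and does not compare them with other genes, passed 15 lists; its adjusted p is given where its call differs from that of camera. The number of called members was the same when adjusted over the list alone, except where stated.

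Genes of the mitochondrial dysfunction stimulon, the nuclear set induced when mitochondrial function is impaired, rose together. Of 22 tested members 20 were higher and none lower, with a median log2 fold change of 1.88 (camera adjusted p = 6.13e-10; adjusted p = 0.0483 with an estimated correlation); SAG21 (0.05), which overlaps another gene, and TIM17-1 (-0.08) did not pass. Besides NDB4 and AT5G09570, the members with the smallest p included AT2G04050, a MATE transporter gene with near-identical relatives (log2 fold change 5.81 ± 0.21, SE), and NAC13 (2.02 ± 0.08), a transcription factor of this response. In the alternative respiration list, 8 of 12 tested genes were higher and NDC1 was lower (-0.47; camera adjusted p = 0.00756; adjusted p = 0.375 with an estimated correlation). The higher genes included NDB3 (3.57 ± 0.23), which overlaps another gene, NDB2 (1.31 ± 0.10) and AOX1A (1.301 ± 0.10). Of 10 retrograde regulators 7 were higher and none lower (camera adjusted p = 0.0241; adjusted p = 0.336 with an estimated correlation), among them NAC016 (1.01 ± 0.15), NAC053 (0.65 ± 0.11) and RCD1 (0.41 ± 0.07). This call ended without wild type replicate 3 (adjusted p = 0.0501; range over camera alternatives 0.0146 to 0.0501). The lists share members and are not separate evidence: NAC13 and NAC053 are also in the stimulon, as are AOX1A and NDB4 of the alternative respiration list. ERF71, AT5G51440, GSTU24 and GSTU25, named below in the hypoxia, chaperone and glutathione S-transferase lists, are stimulon members too.

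Transcripts of the mitochondrial genome were higher almost throughout. Of 62 tested mitochondrial genes, 60 were higher and none lower, with a median log2 fold change of 1.52 (camera adjusted p = 1.98e-25; adjusted p = 0.294 with an estimated correlation). All 37 protein-coding entries of the deposited tables were higher, by 0.78 to 1.95 on the log2 scale. A part of a gene with an entry of its own was counted separately, so the number of genes may be smaller. The median was 1.67 for the 5 cytochrome c maturation entries, 1.64 for the 7 ribosomal protein entries and 1.39 for the 13 complex I entries. It was 1.13 for the 3 complex IV entries and 0.82 for the 6 ATP synthase entries. The differences between these classes were not tested. ccmC (position 308298 to 309068), ccmFN1, ccmFC and ccmB had log2 fold changes of 1.93 ± 0.06, 1.82 ± 0.07, 1.67 ± 0.06 and 1.34 ± 0.05 (SE; edgeR adjusted p of 8.26e-07 or less); ccmC and ccmFC have near-identical nuclear copies. The ribosomal RNA genes rrn26 (0.51) and rrn18 (-0.14, edgeR adjusted p = 0.482) moved less or did not pass, in libraries depleted of ribosomal RNA. The rrn26 call ended with the replicate block and without wild type replicate 1 or 2 or double mutant replicate 1 (adjusted p over alternatives 0.00399 to 0.121). The mitochondrial share of all counts was 1.65% ± 0.0770 in wild type and 4.42% ± 0.202 in the labelled mutant libraries (SD, n = 3 each), a difference of 2.77 percentage points with an exact permutation p = 0.1 (adjusted p = 0.1), the smallest this design allows.

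The nuclear lists of oxidative phosphorylation, mitoribosomal, chaperone and TCA cycle genes did not pass camera as reported. Of 56 nuclear subunits of oxidative phosphorylation, 19 were higher and 6 lower (19 and 5 adjusted over the list alone), with a median log2 fold change of 0.07 (camera adjusted p = 0.114; adjusted p = 0.846 with an estimated correlation), although the list passed without wild type replicate 2 (adjusted p = 0.0218; range over camera alternatives 0.0218 to 0.357). Those with the smallest p were CYTC-2 (0.79 ± 0.09, SE) and the complex II subunits SDH3-1 (0.50 ± 0.06), SDH5 (0.39 ± 0.06) and SDH1-1 (0.37 ± 0.05); SDH3-1 overlaps another gene and shares sequence with SDH3-2. Of 45 nuclear mitoribosomal protein genes, 12 were higher and 3 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.533), with AT5G20180 at 0.81 ± 0.07, AT3G01740 at 0.33 ± 0.06, DECOY at 0.31 ± 0.06 and AT4G28360, which has a near-identical relative, at -0.34 ± 0.07. The other lower genes were AT5G15220 (-0.30), which also has one, and MRPL11 (-0.28). Of 26 chaperone, protease and import genes, 8 were higher and TOM22-V (-0.22) was lower (camera adjusted p = 0.162; fry adjusted p = 0.0368). Among them were the small heat shock protein gene AT5G51440 (2.68 ± 0.13), MGE1 (0.90 ± 0.07), MTHSC70-2 (0.79 ± 0.08), which has a near-identical relative, and TOC64-V (0.61 ± 0.08), which overlaps another gene. Of 20 genes of the TCA cycle and pyruvate dehydrogenase, 8 were higher and mMDH1 (-0.28) was lower (camera adjusted p = 0.0648; adjusted p = 0.755 with an estimated correlation); AT5G65750, a 2-oxoglutarate dehydrogenase subunit, had 1.13 ± 0.06, ACO3 0.63 ± 0.07, mMDH2 0.37 ± 0.10 and IAR4 0.28 ± 0.07. AT5G65750 and mMDH2 overlap other genes. The TOM22-V call ended without wild type replicate 2 or double mutant replicate 3 (adjusted p over alternatives 0.0133 to 0.0643) and that of mMDH1 without double mutant replicate 2 or 3 (0.00494 to 0.0540). The TCA list passed with limma-voom (adjusted p = 0.0427), with no filter on low counts (adjusted p = 0.0425) and without wild type replicate 2 (adjusted p = 0.0262; range over camera alternatives 0.0262 to 0.149), and with fry (adjusted p = 0.0185).

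**Figure D3:**
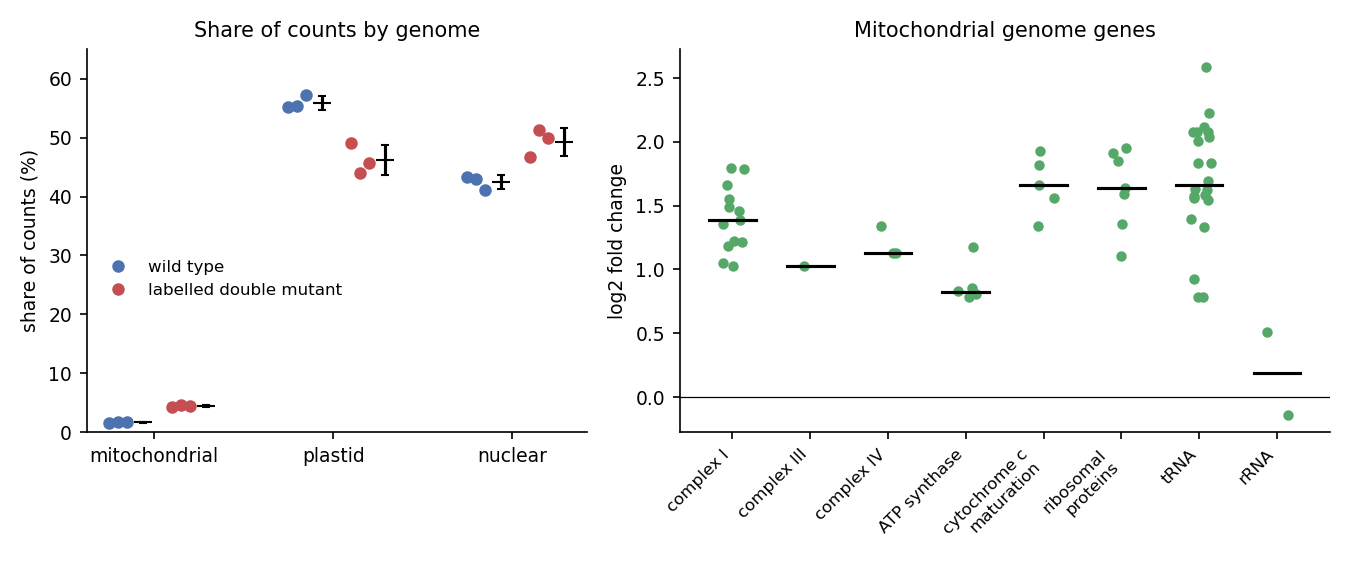
Left, share of all counts (%) on mitochondrial, plastid and nuclear genes, each point a library, with the mean and SD of each group (n = 3) as a bar; the mitochondrial means are 1.65% in wild type and 4.42% in the labelled mutant libraries. Right, log2 fold change (labelled mutant over wild-type libraries) of each tested mitochondrial gene by class, with the class median as a line, from 1.67 for cytochrome c maturation to 0.19 for ribosomal RNA.

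Photosynthesis transcripts were lower from both the nuclear and the plastid genome. Of 46 nuclear photosynthesis genes, 36 were lower and 3 higher, with a median log2 fold change of -0.57 (camera adjusted p = 1.86e-08; adjusted p = 0.704 with an estimated correlation). The Rubisco small subunit genes RBCS3B, RBCS1B and RBCS2B fell by 2.04 ± 0.10, 1.88 ± 0.09 and 1.80 ± 0.08 (SE), but share sequence with each other, and PSBQA, a photosystem II subunit, fell by 1.34 ± 0.08. The 3 higher genes encode light-harvesting proteins of photosystem II: LHB1B2 (0.67), LHCB4.2 (0.67) and LHCB2.2 (0.58); LHB1B2 and LHCB2.2 have near-identical relatives, and the LHCB2.2 call ended without double mutant replicate 3 (adjusted p over alternatives 0.000548 to 0.0514). Of 131 tested plastid genome genes, 120 were lower and none higher (122 lower adjusted over the list alone), with a median of -0.65 (camera adjusted p = 6.31e-22; adjusted p = 0.375 with an estimated correlation). Of 86 plastid protein-coding genes 76 were lower. Reads from near-identical plastid copies were counted at each copy, so such genes, among them trnR, enter these numbers and the list test repeatedly. Transfer RNA genes had the smallest p, with trnY at -1.21 ± 0.08, trnL at -1.13 ± 0.08 and the near-identical copies of trnR at -1.60 ± 0.10. The plastid share of counts was 55.9% ± 1.17 in wild type and 46.3% ± 2.55 in the labelled mutant libraries, and the nuclear share 42.4% ± 1.21 and 49.3% ± 2.37 (SD, n = 3 each; exact permutation p = 0.1 for each). In every library psbA had the most counts.

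Flavonoid and anthocyanin genes rose and sugar starvation genes fell. All 15 tested flavonoid and anthocyanin genes were higher, 13 of them by more than 2-fold, with a median log2 fold change of 5.73 (camera adjusted p = 4.49e-09; adjusted p = 0.336 with an estimated correlation). Besides DFR and AT4G14090, the regulator TT8 rose by 6.17 ± 0.19 (SE), from 0.173 ± 0.0307 to 12.3 ± 1.85 CPM (SD, n = 3 each), and LDOX, which shares sequence with AT4G22870, by 5.80 ± 0.24. Of 20 sugar starvation genes, 12 were lower and 3 higher (camera adjusted p = 0.00823; adjusted p = 0.704 with an estimated correlation). The trehalose-6-phosphate synthase family genes TPS11 and TPS9 had -3.03 ± 0.18 and -1.997 ± 0.14, and DIN4, a subunit of branched-chain keto acid dehydrogenase, -0.91 ± 0.06, beside DIN10. The 3 higher members were DIN2 (2.86), BCAT-2 (2.03) and GDH1 (0.19), which has a near-identical relative. The GDH1 call ended with the DESeq2 Wald test and without wild type replicate 1 or 2 or double mutant replicate 2 or 3 (adjusted p over alternatives 0.0241 to 0.129).

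**Figure D4:**
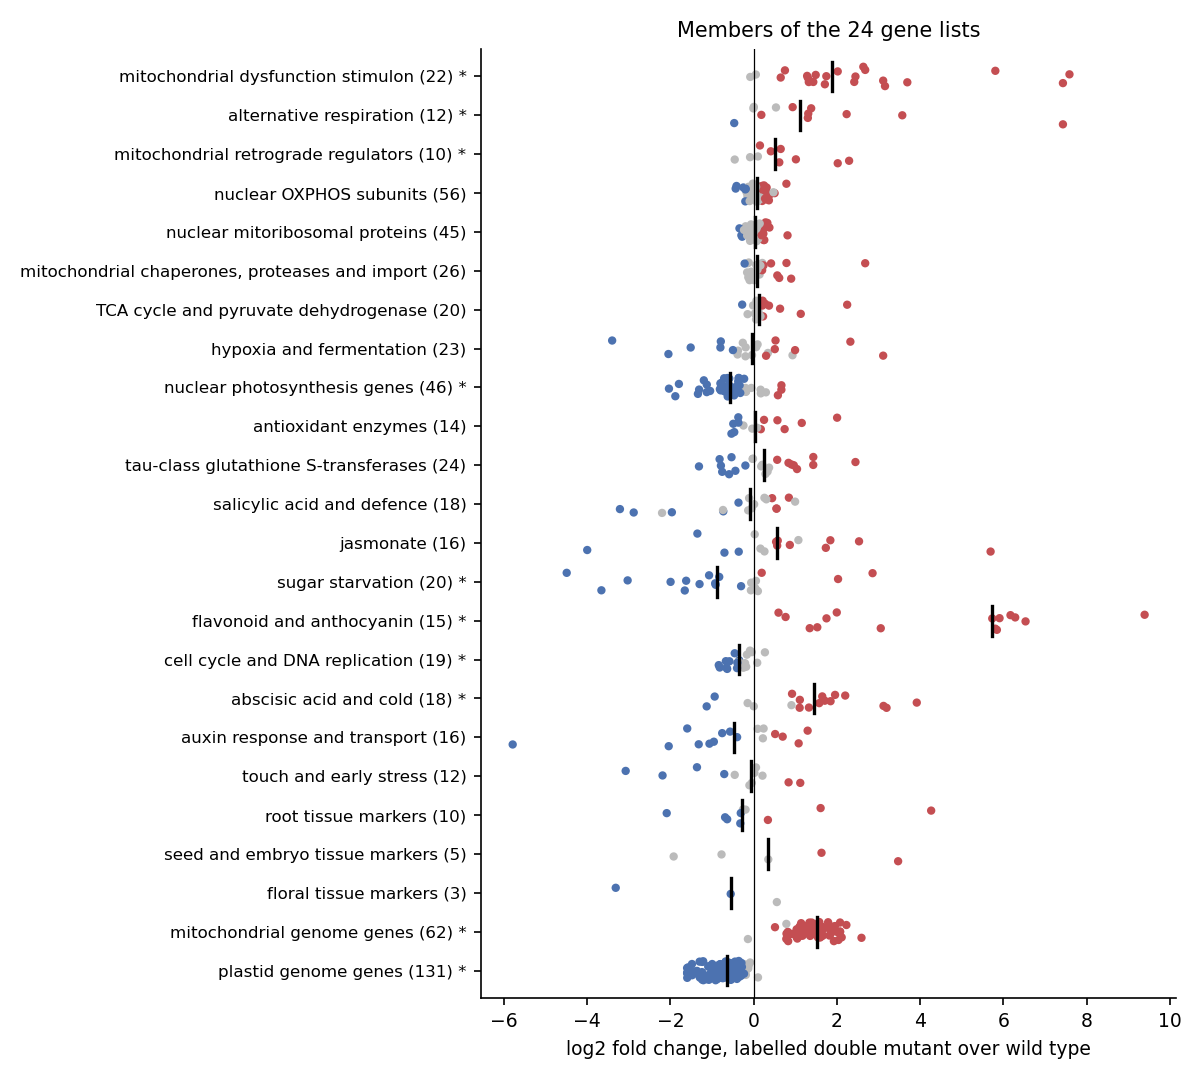
Log2 fold change (labelled mutant over wild-type libraries) of each tested member of the 24 lists, with the number of tested members in brackets and the list median as a black line. Members with an edgeR adjusted p under 0.05 are red where higher and blue where lower, others grey, and a star marks the 10 lists that passed camera with the preset correlation; the medians run from 5.73 for flavonoid and anthocyanin genes to -0.87 for sugar starvation genes.

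Abscisic acid and cold genes were higher in 13 of 18 cases, and COR15B (-1.13) and COR47 (-0.94) were lower (camera adjusted p = 0.00251; adjusted p = 0.704 with an estimated correlation). RD22, COR15A, the proline synthesis gene P5CS1 and the phosphatase gene ABI1 had log2 fold changes of 2.199 ± 0.09, 1.85 ± 0.13, 1.65 ± 0.11 and 1.33 ± 0.13 (SE); P5CS1 shares sequence with P5CS2. Of 19 genes of the cell cycle and DNA replication, 10 were lower and none higher (camera adjusted p = 0.00756; adjusted p = 0.755 with an estimated correlation), including CYC1BAT (-0.84 ± 0.13), SYP111 (-0.82 ± 0.11), CDC20.2 (-0.65 ± 0.11) and CDKB1;2 (-0.64 ± 0.11). CYC1BAT and CDC20.2 have near-identical relatives. The cell cycle call ended with the DESeq2 Wald statistic (adjusted p = 0.0562; range over camera alternatives 0.000629 to 0.0562) and with fry (adjusted p = 0.0735).

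Other hormone and stress lists did not pass camera and held members that went both ways. Of 16 jasmonate genes 8 were higher and 4 lower (camera adjusted p = 0.114, and 0.0104 with the DESeq2 Wald statistic, in a range over camera alternatives of 0.0104 to 0.845; adjusted p = 0.755 with an estimated correlation and 0.0178 with fry): VSP2 had 2.53 ± 0.15, CORI3 1.84 ± 0.13, AOC1 1.73 ± 0.19 and AOS 0.58 ± 0.08 (SE), and the repressors JAZ7 (-4.00 ± 0.58), TIFY7 (-1.35), JAZ10 (-0.70) and TIFY10B (-0.36) were lower. The JAZ10 call ended without wild type replicate 2 or 3 or double mutant replicate 1 or 3 (adjusted p over alternatives 0.00215 to 0.152). That of TIFY10B ended without wild type replicate 2 or 3 or double mutant replicate 2 (0.000594 to 0.0641). VSP2 and AOC1 have near-identical relatives. The list mean of 0.59 was -0.24 with no filter on low counts and -0.39 to -0.05 without wild type replicate 1 or any of the labelled mutant libraries, when low-count members entered the list. Of 16 auxin genes 4 were higher and 9 lower (camera adjusted p = 0.152; fry adjusted p = 0.000137), with the auxin-inducible IAA6 at -5.79 ± 0.43, IAA19 at -2.04 ± 0.17, SAUR15 at -1.60 ± 0.24 and IAA2 at -1.32 ± 0.07. The 4 higher genes were LBD16 (1.296), GH3.3 (1.08), which has a near-identical relative, WES1 (0.70) and PIN7 (0.52). IAA6 was at 1.775 CPM in wild type and 0.0293 CPM in the labelled mutant libraries, and SAUR15 at 0.504 and 0.167 CPM. The fold changes of IAA6 and SAUR15 thus rest on few counts. Of 18 salicylic acid and defence genes 4 were higher and 5 lower (camera adjusted p = 0.829), with ALD1 at -3.21 ± 0.48, PR5 at -1.97 ± 0.32, EDS5 at -0.73 ± 0.09 and SAG101 at 0.55 ± 0.08. ALD1 was at 0.484 CPM in wild type and 0.0505 CPM in the labelled mutant libraries, so its fold change rests on few counts. The other called members were SARD1 (0.85), EDS16 (0.55), the salicylic acid synthesis gene also called ICS1, PAD4 (0.44), EDS1 (-0.37), which has a near-identical relative, and BGL2 (-2.88 ± 0.93). BGL2 was at 15.3 CPM in wild type replicate 3 against 0.268 and 5.24 in the other wild-type libraries, and had -1.57 without it (adjusted p = 0.158; range over alternatives 0.000367 to 0.283). Its call also ended with limma-voom and without any one of the labelled mutant libraries. The SARD1 call ended with the DESeq2 Wald test and without wild type replicate 2 or 3 or double mutant replicate 1 or 2 (0.00860 to 0.152), and that of PAD4 without wild type or double mutant replicate 3 (0.00568 to 0.0584). Of 12 touch and early stress genes TCH4 (-3.08 ± 0.49), TCH3 (-2.19 ± 0.23), TCH2 (-1.36 ± 0.17) and WRKY53 (-0.71) were lower, and ERF5 (1.12 ± 0.26) and STZ (0.84) higher (camera adjusted p = 0.357); TCH3 has a near-identical relative. The STZ call ended with the DESeq2 Wald test and without wild type replicate 2 or double mutant replicate 1 or 3 (adjusted p over alternatives 0.0104 to 0.0937). Without double mutant replicate 2 TCH4 had -4.03, ALD1 -3.835 and JAZ7 -4.615.

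The hypoxia and fermentation list had 6 higher and 6 lower of 23 (camera adjusted p = 0.796), with ERF71 at 3.11 ± 0.27, PPDK at 2.32 ± 0.06, PDC2 at 0.99 ± 0.08 and ACHT5 at -3.40 ± 0.10 (SE). Wild type replicate 2 stood apart from the other wild-type libraries in this list, with ADH1 at 20.7 CPM against 4.93 and 6.69, AT4G33070 at 23.1 against 6.38 and 7.53, and SUS4 at 20.23 against 4.65 and 5.64, genes chosen after their values were seen. None of these genes passed, but without this library all of them were higher, by 1.83, 1.17 and 0.73 (adjusted p = 5.22e-05, 0.000215 and 0.00264; over all alternatives up to 0.268, 0.933 and 0.990). ADH1 also passed with limma-voom and with the replicate block. Without wild type replicate 2 the list mean turned from -0.06 to 0.29 (camera adjusted p = 0.0764; range over camera alternatives 0.0764 to 0.943). Of 14 antioxidant genes 6 were higher and 5 lower (camera adjusted p = 0.661; fry adjusted p = 0.0322); DHAR1, which has a near-identical relative, had 2.00 ± 0.09, CAT3 1.16 ± 0.09, GPX6 0.74 ± 0.08 and CAT1 -0.49 ± 0.06. The other lower genes were FSD1 (-0.53), APX1 (-0.47), FSD2 (-0.37), which has a near-identical relative, and FSD3 (-0.37). The FSD3 call ended without wild type replicate 2 or any one of the labelled mutant libraries (adjusted p over alternatives 0.00702 to 0.0798). Of 24 tau-class glutathione S-transferase genes 8 were higher and 8 lower (camera adjusted p = 0.533), with GSTU25 at 2.45 ± 0.18, GSTU24 at 1.43 ± 0.14, GSTU10 at 1.04 ± 0.16 and GSTU16 at 0.84 ± 0.13. GSTU10 overlaps another gene.

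Lists of root, seed and floral markers did not pass camera. The root marker CASP1 was at 8.28 CPM in wild type, so these seedling libraries may hold root RNA. Of 10 root markers 3 were higher and 5 lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.533), with the nitrate transporter gene NRT2:1, which has a near-identical relative, at 4.26 ± 0.15 and the endodermal gene CASP1 at -2.09 ± 0.24 (SE). IRT1 (1.61) and SHR (0.34) were also higher, and SHV2 (-0.69), MYB66 (-0.64), SCR (-0.32) and PHT1;1 (-0.31), which has near-identical relatives, lower. Without wild type replicate 2 or 3 or double mutant replicate 2 or 3 the calls of SHR and SCR ended (adjusted p over alternatives 0.00460 to 0.119 and 0.0149 to 0.119). That of PHT1;1 ended without wild type replicate 1 or 2 or double mutant replicate 2 or 3 (0.00584 to 0.121). That of SHV2 ended with limma-voom and without wild type replicate 1 or 3 or double mutant replicate 2 or 3 (0.00683 to 0.131). Of 5 tested seed and embryo markers FUS3 (3.47 ± 0.34) and GEA6 (1.63 ± 0.60) were higher (1 gene adjusted over the list alone; camera adjusted p = 0.502), both under 1 CPM in every library. Of 3 tested floral markers SEP3 (-3.32 ± 0.36) and AGL8 (-0.55 ± 0.19) were lower (camera adjusted p = 0.373; fry adjusted p = 0.00189). The calls of GEA6 and AGL8 ended with the DESeq2 Wald test and in several fits with a library left out. Without wild type replicate 3 the log2 fold changes of GEA6 and FUS3 were 3 and 4.09, and over all alternatives that of GEA6 was 1.24 or more. Without double mutant replicate 2 that of SEP3 was -4.15. The median, mean and test differed in sign for the root list (median -0.28, mean 0.17, camera lower, fry higher) and the hypoxia list (median -0.04, mean -0.06, camera and fry higher).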

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

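The fit without nuclear genes that share organelle sequence, and the further lists without members seen beforehand, were chosen after the data were seen; the other alternatives were fixed before. The number of changed genes stayed between 9511 and 11526 in all fits at the same threshold (11421 as reported), no gene called both there and in another fit changed sign, and each scaling moved the median log2 fold change by 0.013 or less. TMM and DESeq2 size factors both centre fold changes on the bulk of genes, so their near-equal medians do not test that centring. With a 2-fold threshold 2965 genes were called, because the rule is stricter. The log2 fold change of AT3G21465 kept its sign and passed in every fit; that of AT4G15640 ranged from 0.11 to 0.24 over fits with a library left out and passed only without wild type replicate 2. Between 8 and 12 lists passed camera with the preset correlation (10 as reported; 8 with nuclear genes only, where both organelle lists are absent), 1 with estimated correlations and 15 with fry. Without psbA the difference in mitochondrial share was 3.32 percentage points (2.77 with it) and that in nuclear share 4.71 (6.92 with it), because psbA takes a large part of the total. Deviations from the group means correlated at 0.192, 0.0715 and -0.00164 between same-numbered libraries, and at -0.145 to 0.0954 between differently numbered ones. Replicates 2 and 3 did not pair by number. The replicate 1 pair had the highest correlation, so a factor shared by its libraries is not excluded. The replicate block gave 11373 changed genes. Of the named results the block ended only the calls of GEA6 and rrn26, and ADH1 gained a call. Over all alternatives, single named genes, with those named after their values were seen, kept direction and side of the threshold 2137 times, lost the call 75 times and gained it 5 times. SAG21, TIM17-1 and SUS4, none of which passed as reported, changed sign 9 times in all. SUS4 also passed in its sign change without wild type replicate 2 (edgeR adjusted p = 0.00264), which is not among the 5 gains. With a library left out SAG21 (0.05) ranged from -0.0823 to 0.126, TIM17-1 (-0.08) from -0.775 to 0.2299 and SUS4 (-0.26) from -0.594 to 0.7275, and SUS4 was 0.0252 with limma-voom and 0.00616 with the replicate block. Lists kept both 401 times, lost the call 16 times (13 with an estimated correlation) and gained it 11 times (6 with fry, which does not compare a list with other genes). The cause was not tested. No result called as reported changed direction, but the means of 2 lists that did not pass changed sign 8 times. The hypoxia mean (-0.06) was 0.016 with limma-voom, 0.0084 with the replicate block and 0.29 without wild type replicate 2, the highest with a library left out, where the lowest was -0.1985. The jasmonate mean (0.59) was -0.241 with no filter on low counts and between -0.387 and -0.0549 without wild type replicate 1 or a labelled mutant library (-0.351 without wild type replicate 1, -0.229 without double mutant replicate 1), and highest without wild type replicate 2 (0.791). In the fits with a negative mean 2 or 3 members with at most 241 counts in all entered the list, and the mean over the other members stayed between 0.469 and 0.707. At the depth of these libraries AT3G21465, at under 10 CPM, still had at least 340 counts in each, whereas genes under 1 CPM, such as GEA6, rest on few.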

Other observations

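Tests chosen only after the result was seen are the 5 further gene lists, the comparison of mitochondrial genes with and without nuclear copies, the ratio of mitochondrial to nuclear counts, the comparison with nuclear OXPHOS genes and the check for a mislabelled library. Genes of nutrient deficiency were higher in the labelled mutant libraries. All 18 tested phosphate starvation genes were higher, with a median log2 fold change of 2.72 (camera adjusted p over the 5 further lists = 1.58e-09; adjusted p = 0.157 with an estimated correlation). The non-coding RNA gene IPS1, at only 0.0633 CPM in wild type, had 4.52 ± 0.36 (SE). Other examples are PS2 (AT1G73010, 4.39 ± 0.17), the galactolipid synthase gene MGDC (3.90 ± 0.13), SPX1 (3.19 ± 0.19) and PAP17 (3.09 ± 0.21). The count depends on the choice of members: the list holds PHT1;4 but not PHT1;1, which was lower among the root markers. Of 18 tested iron deficiency genes 17 were higher and none lower, with a median of 1.90 (camera adjusted p = 1.78e-06; adjusted p = 0.245 with an estimated correlation). bHLH38 had 3.99 ± 0.60, and 4.98 without wild type replicate 2, CYP82C4, which has near-identical relatives, 3.61 ± 0.32, FRO2 1.82 ± 0.23 and IRT1 1.61 ± 0.24. For bHLH38 wild type replicate 2 was at 2.83 CPM against 0.640 and 0.820 in the other wild-type libraries, and double mutant replicate 1 at 9.03 CPM against 28.99 and 32.7 in the other labelled mutant libraries. Some members had been seen among the most changed genes when the lists were written; without these, 15 of 15 phosphate starvation genes (camera adjusted p = 7.08e-08; adjusted p = 0.186 with an estimated correlation) and 13 of 14 iron deficiency genes were higher (camera adjusted p = 7.36e-05; adjusted p = 0.33 with an estimated correlation). Members of the full lists were correlated (estimated 0.358 and 0.466), so the remaining genes are not independent of those seen.

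A list of starch synthesis and turnover held members that went both ways. Of 19 genes 14 were higher and 3 lower, with a median log2 fold change of 0.33 (camera adjusted p = 0.00166; adjusted p = 0.342 with an estimated correlation). These p-values include GBSS1, APL3 and GPT2, which had been seen among the most changed genes. Without them 11 of 16 were higher and 3 lower, with a median of 0.27 and a mean of 0.44 (camera adjusted p = 0.0291; adjusted p = 0.551 with an estimated correlation). The granule-bound starch synthase gene GBSS1 rose by 5.97 ± 0.15 (SE), the ADP-glucose pyrophosphorylase genes APL3 and APL4 by 3.57 ± 0.10 and 3.26 ± 0.09, and the branching enzyme gene SBE2.2 by 1.32 ± 0.06. The leaf form APL1 (-0.43 ± 0.08), PGM (AT5G51820, -0.54 ± 0.09) and SS4 (-0.80 ± 0.07) were lower. All examples in these paragraphs were chosen after their values were seen.

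Higher transcripts of the mitochondrial genome were weighed against repeated counting and scaling, and compared with nuclear genes for the same complexes. Reads counted again at copies in annotated nuclear genes would leave mitochondrial genes without such a copy near 0. The 14 mitochondrial protein-coding entries without a near-identical nuclear gene had a median log2 fold change of 1.363, against 1.355 for the 23 entries with such a gene. Nuclear copies outside annotated genes were not searched for, so the 14 entries may have them and these values do not address such copies. A scaling effect of the many plastid counts would vanish against nuclear counts alone, but the median log2 ratio was at least 1.398 in each of the 9 pairs of libraries. The nuclear OXPHOS list had a median of 0.07012, with 19 genes higher and 6 lower of 56. Nuclear genes for these complexes thus did not rise to a matching extent, but this comparison excludes no cause. The other values argue against copies in annotated nuclear genes, and against scaling, as the whole cause. A hypothesis is that mitochondrial transcript level or stability, or the amount of mitochondrial genome, may differ in the labelled mutant. Counts per gene do not separate these.

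The level of AT4G15640 was weighed next. No gene is near-identical to it (0 found), which argues against reads from a copy. A single mislabelled library is argued against by AT3G21465 and AOX1A, for both of which all 3 labelled mutant libraries lie outside the wild-type range; this does not test whether all 3 carry another genotype than labelled. A transcript that persists around an insertion or small edit remains a candidate explanation: with a log2 fold change of 0.16 from a single count per gene, intact and interrupted transcripts cannot be told apart.

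Lower sugar-repressed genes with higher anthocyanin genes were seen in the fit without each library in turn. There 12 of 12 camera tests with the preset correlation passed with the same sign, so a single deviating library is argued against. In the fit of all libraries neither list passed with an estimated correlation (camera adjusted p = 0.704 for sugar starvation and 0.336 for flavonoid and anthocyanin). Harvest at another time of day may contribute. The 4 morning clock genes had a median log2 fold change of 2.12 (CCA1 3.01, PRR9, which has a near-identical relative, 2.97, LHY 1.27 and PRR7 0.94; all higher; camera adjusted p = 0.00437; adjusted p = 0.157 with an estimated correlation), whereas the 5 evening clock genes had -0.09 (GI and PRR5 higher, TOC1 lower; camera adjusted p = 0.853). Levels of CCA1, PRR9 and LHY were low, with wild-type means of 0.258, 0.316 and 0.179 CPM and labelled mutant means of 2.15, 2.50 and 0.413 CPM. PRR7 went from 23.96 to 46.11 CPM. The median of the morning genes therefore rests on genes with few counts. The LHY call ended without wild type replicate 2 or 3 or double mutant replicate 1 or 2 (adjusted p over alternatives 0.00955 to 0.0801) and that of TOC1 without double mutant replicate 3 (0.00134 to 0.0628). The rule used took opposite moves of both sets as a sign of a time shift, and both near 0 as a sign of none. The values met neither. A shift need not move all evening genes the same way, and these went both ways, so the rule cannot decide. A time difference and a genotype effect on these genes cannot be told apart.

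With 3 against 3 libraries there are only 10 splits, too few for a share under 0.05. The real split gave 11421 changed genes, 1 of 10 splits with as many. The highest of the others gave 0 by edgeR at the adjusted threshold and 319 at an unadjusted p under 0.05, against 12674 in the real split. Every other split mixes both groups, so the difference between the groups enters the spread within each side. Few calls in those splits were therefore bound to follow, and this contrast does not test chance or a batch.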
